A study of Mus musculus with 10 samples.

How the data were processed

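Polyadenylated RNA of EpCAM-sorted mouse cholangiocytes, the epithelial cells that line the bile ducts, was measured in 10 libraries. Per the labels, the mice were wild type and had received a lentiviral vector on post-natal day 1. GFPpos names cells that carried the vector's green fluorescent marker and GFPneg names cells that did not, with 5 libraries in each group. The age at which cells were taken, the promoter of the vector and the number of cells sorted are not given in the sources used here. Per the labels' protocols, RNA was extracted with a micro column kit and amplified to cDNA with SMART-Seq v4, which keeps no strand information.

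The deposited values are whole-number read counts per gene, made by the authors and not normalised. Per the submitters' processing notes, reads were trimmed with Trim Galore, aligned with STAR 2.7.6a and counted with featureCounts of the Subread package. Per the file headers, featureCounts 2.0.1 counted reads by gene name against the mouse GENCODE vM25 annotation, without strand, with an overlap of at least 10 bases. No option for multi-mapping or overlapping reads stood in the header, so by that tool's defaults such reads were left out. Genes with near-identical copies and exons shared between genes are therefore under-counted. The processing notes name the human build GRCh38, whereas the annotation in the header is of the mouse, so coordinates are given as the count table lists them, on the mouse build of that annotation (GRCm38). The table held 55367 gene names and no row for the vector or its marker.

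Gene counts summed to between 33847069 and 76482387 per library. At these totals, 3 counts, taken as the floor for a gene with a count of 0, came to between 0.0392 and 0.0886 CPM (counts scaled to a common library total). Floors and intervals cover counting error only, since amplified reads without molecular identifiers are not independent molecules. Within groups, all 20 pairs of libraries differed by far more than sampling noise (chi-square per degree of freedom from 87.7 to 478.4), and no library was counted as a duplicate.

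Groups came from the labels. Genes were kept with edgeR's filterByExpr by group, which left 15327 genes holding 99.9% of all counts, and libraries were scaled by TMM. The comparison was fitted with edgeR 4.0.16 (quasi-likelihood, robust, two-sided, R 4.3.3) and Benjamini-Hochberg adjustment, and a gene was called changed at an adjusted p under 0.05. Log2 fold changes are given with their SE, and CPM values are TMM-normalised means with SD over n = 5 libraries. The SE was not fitted directly but taken as the size of the log2 fold change over the square root of the test's F value. The replicate numbers 2, 3, 4, 8 and 9 occur in both groups. Same-numbered libraries deviated together from their group means in 5 of 5 pairs (correlations from 0.10 to 0.38, median of different numbers -0.061), and 8 of 10 libraries correlated best with their own number. In 5 of 5 pairs Xist and the Y-linked Ddx3y pointed to the same sex within the pair, so the numbers were taken to pair the libraries. The pairs were of both sexes: Xist stood at 111 to 172 CPM in libraries numbered 4 and 9, and Ddx3y at 101 to 144 CPM in those numbered 2, 3 and 8. Sex is therefore part of the spread in a fit without the replicate block. This pairing comes from the labels' numbers and the data, since no label names an animal. The fit without the block was fixed as the main fit and the fit with the block as an alternative. As no label says that libraries came from separate animals, p-values measure the spread between these libraries.

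A total of 39 gene lists were fixed before the data were examined. They covered liver and biliary cell types, liver metabolism, signalling and stress pathways, and other cell types that a liver sort could hold. Some lists share genes, so results of such lists are not separate evidence. Lists with at least 5 measured members (37 lists) were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, two-sided, with adjustment over these lists. Per list, members past the threshold were counted over all genes tested and, separately, adjusted over the list alone. The shares of counts in the hepatocyte and the biliary list were compared by an exact two-sided permutation test over all 252 assignments, whose smallest possible p is 0.00794. This test takes no account of the pairing by replicate number. A sign-flip test of the 5 pairs cannot give a p below 0.0625.

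Genes were named by a rule fixed beforehand. It takes the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM in a group and 1 direction in all 5 pairs, leaving out unnamed gene models. It adds up to 4 members with the smallest p of each list described, and 11 fixed genes, of which 1 is not reported here, nor is 1 of the lists. Of these genes Cyp7a1 (0 counts in all libraries) and Ptprc (16 counts in GFPneg and 122 in GFPpos) fell under the filter. Other genes named are marked as chosen after their values were seen.

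The alternatives were a replicate block, DESeq2 1.42.0 with and without the block, its size factors in edgeR, library size only, upper-quartile scaling, no filter, a filter of 10 counts in all 5 libraries of a group, limma voom with quality weights, a test against a fold of 1.5, and leaving out each library. List tests were repeated with an estimated correlation and with fry. Fits without both libraries numbered 2 and with the level of the stress list as a covariate, and the biliary share without Clu and Spp1, were added after seeing the data.

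The scripts were tested on simulated counts for 14552 genes with the libraries' own means, totals and dispersions, in which 200 genes were changed. edgeR recovered 0% of genes set to a fold of 1.5, 16.4% at a fold of 2 and 50.0% at a fold of 4, with 3 false calls among 47 and no call in the wrong direction. With the replicate block it recovered 0%, 4.48% and 40.9%. DESeq2 recovered 2.99%, 43.3% and 62.1%, with 39 false calls among 111. The simulation drew genes independently, so it does not test list results under correlated genes. It held no effect of the replicate number, so it does not test what the block gains from pairing. It changed 200 genes where 907 were called in the data, so recovery in the data may differ.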

Results

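RNA sequencing was performed on EpCAM-sorted cholangiocytes from livers of wild-type mice given a lentiviral vector on post-natal day 1. Cells that carried the vector's green fluorescent marker (GFPpos) were compared with cells from the same kind of sort that did not (GFPneg), with n = 5 libraries per group. The comparison addressed how biliary cells with the vector's marker differ from those without it. Total gene counts ranged from 33847069 to 76482387 in GFPneg and from 46729529 to 73989787 in GFPpos libraries, and no difference between the groups was detected (exact permutation test, two-sided, p = 0.659). Genes with at least 10 counts numbered 15625 on average in GFPneg and 14551 in GFPpos (exact permutation p = 0.206). After all libraries were thinned to the smallest total, they numbered 14745 and 13614 (exact permutation p = 0.095). The 20 most abundant genes held 16.6% to 19.2% of counts in GFPpos libraries and 14.4% to 16.1% in GFPneg libraries.

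GFPpos cells had higher levels of 7 of 28 hepatocyte genes and of 17 of 26 immediate early and heat shock genes, and lower levels of 7 of 17 mucin and peribiliary gland genes, than GFPneg cells. The camera call of the hepatocyte list as a whole was lost with an estimated correlation (adjusted p = 0.138). Alb, which encodes serum albumin, averaged 2861 ± 704 CPM in GFPpos and 817 ± 255 CPM in GFPneg libraries (SD, n = 5), a 3.50-fold difference (chromosome 5, 90460897 to 90476602, mouse build GRCm38 as are all positions here). Dmbt1, a secreted scavenger receptor of mucosal epithelia, was 10.4-fold lower, at 1242 ± 218 CPM against 12875 ± 1927 CPM (chromosome 7, 131032046 to 131121628). Epcam, the surface protein used for the sort, was at 1793 ± 236 CPM in GFPpos and 2032 ± 276 CPM in GFPneg, lower in GFPpos in 5 of 5 same-numbered pairs, and did not pass the test (adjusted p = 0.535; chromosome 17, 87635979 to 87651129). Of 15327 genes tested with edgeR's quasi-likelihood test, 907 passed an adjusted p of 0.05, of which 409 were higher and 498 lower in GFPpos. The count fell to 550, 568 or 433 when GFPneg replicate 2, 3 or 8 was left out, and to 553 without both libraries numbered 2. In those 4 fits all main calls that were tested kept their direction.

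**Figure D1:**
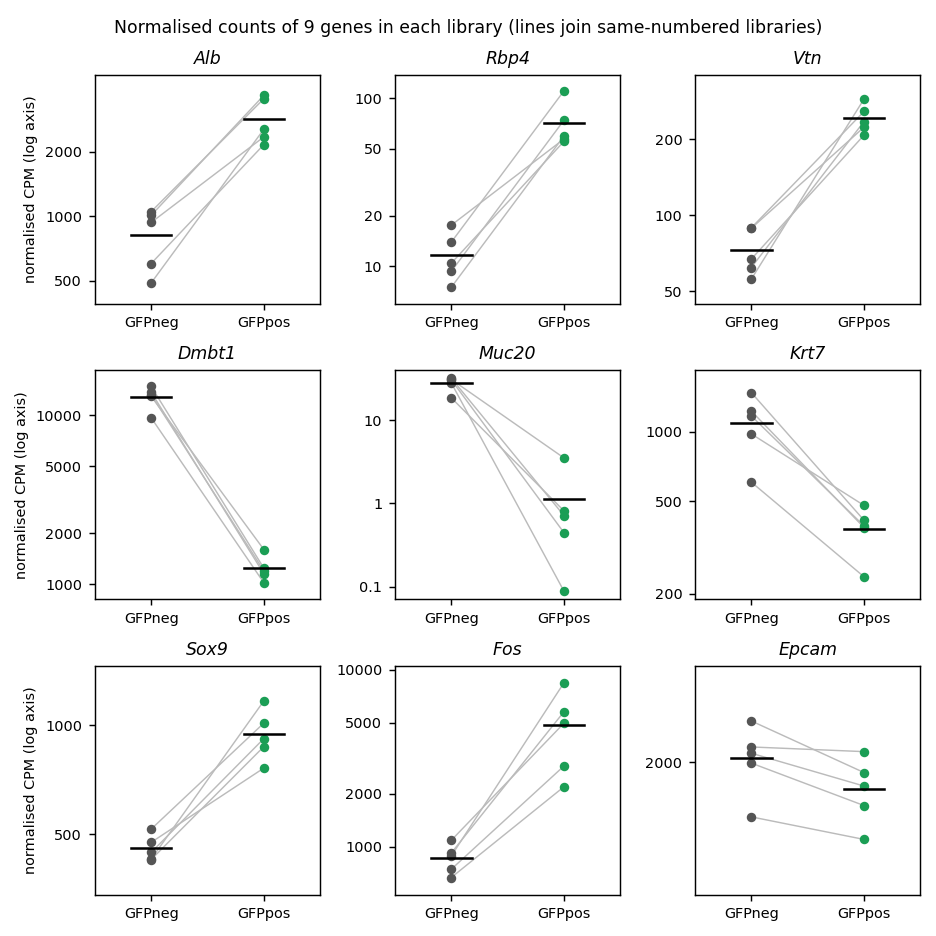
Normalised read counts in CPM (log axis) of 9 genes in each of the 10 libraries; dots are libraries, black bars are group means and grey lines join libraries with the same replicate number. Alb, Rbp4, Vtn, Sox9 and Fos were higher and Dmbt1, Muc20 and Krt7 lower in GFPpos in all 5 pairs, while Epcam (2032 CPM in GFPneg, 1793 CPM in GFPpos) was also lower in all 5 pairs but did not pass the test.

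The 10 largest rises included genes of the liver's plasma proteins and transcription factors. Hamp, which encodes the iron hormone hepcidin, rose from 2.78 ± 1.69 to 21.2 ± 8.40 CPM (log2 fold change 2.93 ± 0.51, adjusted p = 0.0062; chromosome 7, 30942368 to 30944032). Rbp4, the plasma carrier of retinol, rose from 11.8 ± 4.01 to 71.3 ± 23.1 CPM (2.60 ± 0.29, adjusted p = 0.00057; chromosome 19, 38116629 to 38125281). Kcne3, a potassium channel subunit, rose by 2.66 ± 0.51 on the log2 scale, and the transcription factors Atoh8, Klf2 and Fos rose by 2.57 ± 0.53, 2.52 ± 0.36 and 2.49 ± 0.33. Nrep rose by 2.49 ± 0.48, and Serpind1 (heparin cofactor II), Krtap17-1 and Fam71a by 3.22 ± 0.76, 3.22 ± 0.70 and 2.74 ± 0.63. The calls of these last 3 were lost when single libraries were left out. Serpind1 was not called without GFPneg replicate 2, 3, 8 or 9 or GFPpos replicate 2 (adjusted p up to 0.080, without GFPneg replicate 8), and Krtap17-1 without GFPneg replicate 2, 3 or 8 (up to 0.070, without GFPneg replicate 8). Fam71a was not called without GFPneg replicate 3 or 9 or GFPpos replicate 3 (up to 0.068, without GFPneg replicate 3). With the replicate block Krtap17-1 and Fam71a had adjusted p values of 0.065 and 0.080.

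The 10 largest falls reached GFPpos means near or below 1 CPM. Among all calls, 66 lower ones had a GFPpos mean under 1 CPM, whereas 2 higher ones had a GFPneg mean under 1 CPM. Whether drop-out of low transcripts in GFPpos libraries gave part of these falls was not tested. Muc20, a membrane mucin, fell from 28.1 ± 5.48 to 1.12 ± 1.37 CPM (log2 fold change -4.65 ± 0.78, adjusted p = 0.0049). Atp6v0a4, a proton pump subunit, fell from 11.1 ± 3.66 to 0.292 ± 0.225 CPM (-5.23 ± 0.67, adjusted p = 0.0012), and Ntn1, which encodes the guidance cue netrin 1, from 10.2 ± 2.63 to 0.361 ± 0.218 CPM (-4.81 ± 0.70, adjusted p = 0.0023). Ret, a receptor tyrosine kinase, changed by -5.15 ± 1.08, the sodium/proton exchanger gene Slc9a4 by -4.97 ± 0.99, the mucosal chemokine gene Ccl28 by -4.89 ± 0.94 and Lypd6 by -5.44 ± 1.02 on the log2 scale. Galnt6, which starts mucin-type O-glycosylation, changed by -4.96 ± 1.15, the cholesterol transporter gene Npc1l1 by -4.67 ± 1.06 and the inflammasome sensor gene Naip2 by -5.32 ± 1.16. Calls of these last 3 were lost when single libraries were left out: Galnt6 without GFPneg replicate 2, 3 or 8 or GFPpos replicate 9, and Npc1l1 without GFPneg replicate 2, 3 or 8 or GFPpos replicate 8 or 9 (adjusted p up to 0.066 for both, without GFPneg replicate 8). Naip2 was not called without GFPneg replicate 3, 8 or 9 (up to 0.051, without GFPneg replicate 3). With the replicate block, adjusted p was 0.053 for Npc1l1 and 0.066 for Naip2. Exons of other genes cover 21.3% of the exonic bases of Slc9a4, 15.6% of Muc20 and 11.4% of Galnt6, where reads were not counted.

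Of 28 measured members of the hepatocyte list, 7 rose and 0 fell over all genes tested, and 13 rose when adjusted over the list alone. Vtn (vitronectin) rose by 1.74 ± 0.17 on the log2 scale to 242 ± 31.6 CPM, Rbp4 and Alb as given above, and Fgg (fibrinogen gamma) by 2.27 ± 0.37 to 203 ± 44.4 CPM, each in 5 of 5 pairs. The share of counts on the list was 0.772 ± 0.170% in GFPpos and 0.391 ± 0.050% in GFPneg libraries (exact permutation test, two-sided, p = 0.00794, the smallest possible, higher in 5 of 5 pairs). Without Alb the difference fell from 0.382 to 0.185 percentage points. The camera test called the list (median log2 fold change 1.90, adjusted p = 4.3e-13), but not with an estimated correlation (adjusted p = 0.138). Without both libraries numbered 2, 6 members rose. The 10 most abundant hepatocyte transcripts form a list whose members, all but Apoc1, are also in the hepatocyte list, so these lists are not separate evidence. Of these 10 transcripts, 3 rose (5 adjusted over the list alone, and 5 with the replicate block over all genes), namely Apoc1 (2.29 ± 0.30), Alb and Trf, which encodes transferrin (2.21 ± 0.54). The call of Trf was lost without GFPneg replicate 2, 3, 8 or 9 or GFPpos replicate 4 or 9 (adjusted p up to 0.089, without GFPneg replicate 8). Of the same list, Ahsg had a log2 fold change of 2.94 ± 0.91 (adjusted p = 0.088), and the camera call (adjusted p = 1.6e-07) was lost with an estimated correlation (adjusted p = 0.138).

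Several abundant hepatocyte transcripts did not follow Alb. Apoa1, Apoa2, Apoc3, Fabp1 and Serpina3k, chosen after their values were seen, summed to 165.9 CPM in GFPpos replicate 2 and to between 0.0686 and 10.7 CPM in the other GFPpos libraries, against 18.9 CPM in GFPneg replicate 2. Alb stood between 2166 and 3682 CPM in all 5 GFPpos libraries. GFPpos replicate 2 also held more transcripts of other liver cells. The Kupffer cell gene Clec4f was at 34.3 CPM there, at 3.05 CPM in GFPneg replicate 2 and at most 1.23 CPM in the other libraries (a gene chosen after its values were seen). The share of counts on the endothelial list was 0.0308% in GFPpos replicate 2 and 0.00726% in the next GFPpos library. Ptprc, the pan-leukocyte gene, was at most 0.775 CPM in each library, and Pecam1 was at 2.91 ± 3.65 CPM in GFPpos and 0.172 ± 0.197 CPM in GFPneg (adjusted p = 0.20).

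**Figure D2:**
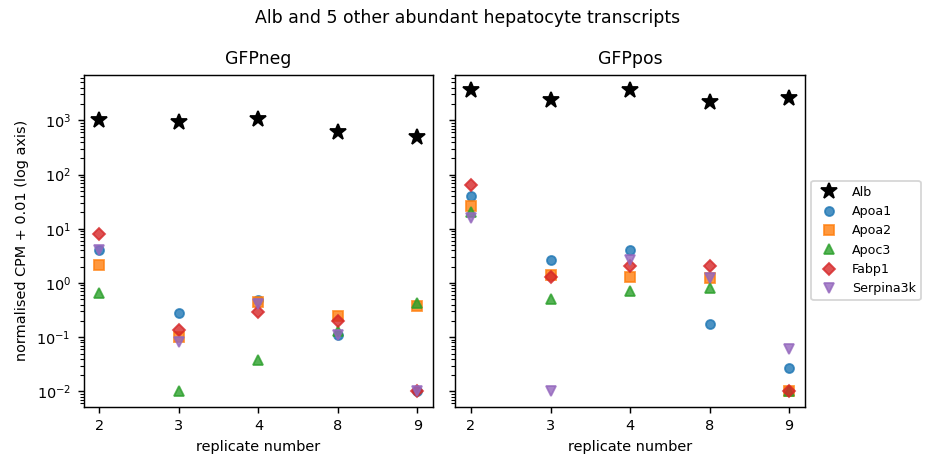
Normalised read counts in CPM plus 0.01 (log axis) of Alb and 5 other abundant hepatocyte transcripts, by replicate number, in GFPneg (left) and GFPpos (right) libraries; each symbol is 1 gene in 1 library. Alb lay between 2166 and 3682 CPM in GFPpos libraries, while the 5 others summed to 165.9 CPM in GFPpos replicate 2 and to at most 10.7 CPM in the other GFPpos libraries.

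Other hepatocyte lists gave smaller counts. Among 19 measured hepatocyte transcription factors, 4 rose, 0 fell, and 15 did not pass; adjusted over the list alone, 7 rose and 1 fell. Prox1 rose by 1.03 ± 0.24 and Rora by 0.81 ± 0.18 on the log2 scale, whereas Hnf4a was at 365 ± 89.1 CPM in GFPpos and 441 ± 92.1 CPM in GFPneg (adjusted p = 0.53). The list was called with the preset (adjusted p = 0.00071) and with an estimated correlation (adjusted p = 0.040). Its 4 gene calls fell to 2 with the replicate block, to 1 without GFPneg replicate 2, to 2 without GFPpos replicate 9 and to 0 without GFPneg replicate 8 or without both libraries numbered 2. Rora was not called without GFPneg replicate 8 or GFPpos replicate 9 (adjusted p up to 0.078), nor Prox1 without GFPneg replicate 2 or 8 or GFPpos replicate 4 (up to 0.071). Of 29 measured lipoprotein and fatty acid genes, 2 rose and 0 fell, both over all genes and adjusted over the list alone: Apoe, a lipoprotein component, from 2410 ± 627 to 9528 ± 1554 CPM (1.98 ± 0.19, adjusted p = 0.00024), and Apoc1. Without GFPpos replicate 3, 3 rose, and without GFPpos replicate 4, 1 fell. Of 17 complement and coagulation genes 3 rose and 0 fell, with the same counts adjusted over the list alone, among them Proc (protein C) by 1.53 ± 0.19, but 1 rose without GFPneg replicate 2, 3, 8 or 9 or GFPpos replicate 2. The camera calls of both lists (adjusted p = 0.030 and 0.032) were lost with an estimated correlation (adjusted p = 0.22 and 0.33). Leaving out GFPpos replicate 4 also ended both (adjusted p = 0.067 and 0.087), and leaving out GFPneg replicate 9 ended that of complement (0.076). The periportal list had 0 rises and 2 falls of 11 (1 and 2 adjusted over the list alone): Cyp2f2, a cytochrome P450, at -2.55 ± 0.27 and Ctsc, cathepsin C, at -1.72 ± 0.19, with a list median of 0.50 (-0.22 with the replicate block), a mean of 0.41 and no camera call (direction down, adjusted p = 0.20). The share of counts on this list was lower in GFPpos in 5 of 5 pairs (0.0665 ± 0.0078% against 0.114 ± 0.017%, exact permutation p = 0.00794).

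Biliary genes moved both ways. Of 34 measured biliary markers, 6 rose, 7 fell and 21 did not pass (13 rose and 9 fell adjusted over the list alone), with a median log2 fold change of -0.04, a mean of -0.07 and no camera call (direction up, adjusted p = 0.55). Sox9, the biliary transcription factor, rose from 459 ± 38.2 to 947 ± 153 CPM (1.05 ± 0.13, adjusted p = 0.0011; chromosome 11, 112782224 to 112787760). Spp1, which encodes osteopontin, rose from 17335 ± 2298 to 31449 ± 2448 CPM (0.86 ± 0.11; 18.8% of its exonic bases lie in exons of another gene), and Bicc1 by 1.19 ± 0.18. Krt7, a keratin of mature ducts, fell from 1091 ± 324 to 382 ± 89.5 CPM (-1.52 ± 0.24, adjusted p = 0.0038; chromosome 15, 101411043 to 101430313), the water channel gene Aqp1 from 236 ± 153 to 32.6 ± 12.2 CPM (-2.85 ± 0.42), and Krt19 changed by -0.97 ± 0.24. Krt19 was not called without GFPneg replicate 2, 3, 8 or 9 or GFPpos replicate 2 or 3 (adjusted p up to 0.089, without GFPneg replicate 8). Falls numbered 3 without GFPneg replicate 2 or 8 or GFPpos replicate 2, and 4 without GFPneg or GFPpos replicate 3. Without GFPneg replicate 8, 3 rose, and without both libraries numbered 2, 4 rose and 2 fell. The share of counts on the list was 11.2 ± 0.48% in GFPpos and 8.91 ± 0.54% in GFPneg libraries (exact permutation p = 0.00794, the smallest possible, higher in 5 of 5 pairs). This difference of 2.32 percentage points rested on the 2 most abundant members. It was 1.45 without Clu and 0.147 without Clu and Spp1 (exact permutation p = 0.651).

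Mucin and peribiliary gland genes fell. Of 17 measured members, 7 fell and 0 rose (11 fell adjusted over the list alone), and all 17 fold changes were negative (median -2.19). Besides Dmbt1 (-3.37 ± 0.16, adjusted p = 1.1e-06) and Muc20, Fcgbp, a mucus-binding protein gene, fell from 150 ± 37.9 to 18.4 ± 12.6 CPM and Gcnt3, which builds mucin glycan branches, from 66.5 ± 27.9 to 4.70 ± 6.79 CPM. The camera call (adjusted p = 1.1e-18) held with an estimated correlation (adjusted p = 0.040). Of 15 progenitor and hybrid markers, 1 rose (Sox9) and 2 fell (1 and 5 adjusted over the list alone), namely Cd44, a hyaluronan receptor, at -1.80 ± 0.25 and the integrin gene Itga6 at -0.75 ± 0.19. The call of Itga6 was lost with each library left out but GFPpos replicate 9 (adjusted p up to 0.115, without GFPneg replicate 8) and with the replicate block (adjusted p = 0.081).

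**Figure D3:**
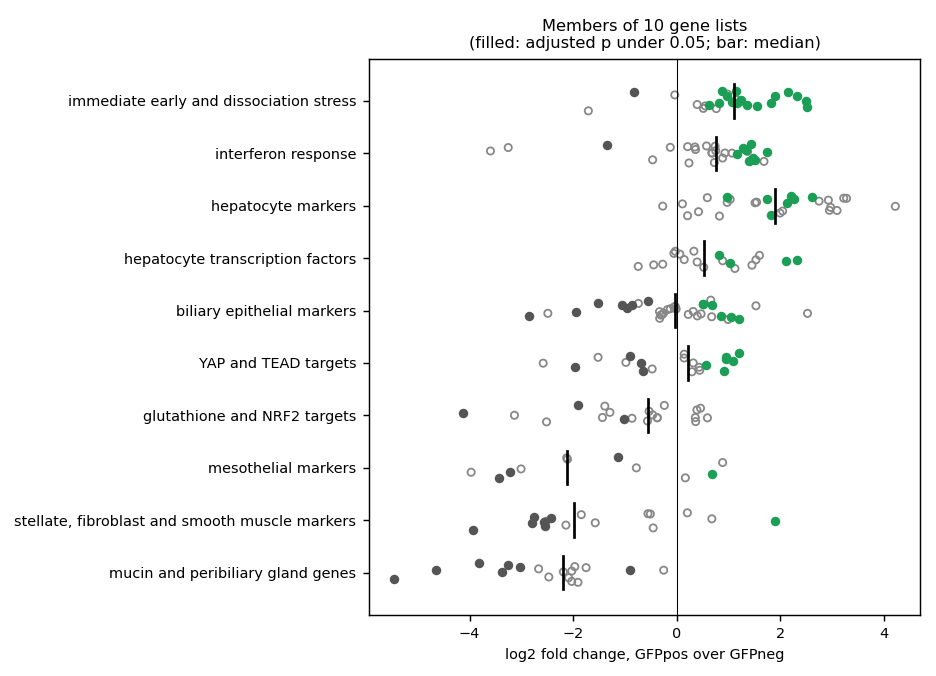
Log2 fold changes (GFPpos over GFPneg) of the measured members of 10 gene lists; filled dots passed an adjusted p of 0.05 (green higher, dark grey lower in GFPpos), open dots did not, and bars are list medians. The mucin list has 7 filled dots, all below 0, and the immediate early list has 17 filled dots above and 1 below 0.

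Most immediate early and heat shock genes rose. Of 26 measured members, 17 rose and 1 fell (22 and 1 adjusted over the list alone), with a median log2 fold change of 1.10. Fos rose from 864 ± 162 to 4848 ± 2486 CPM (2.49 ± 0.33, adjusted p = 0.0013) and Fosb by 2.14 ± 0.23. The heat shock genes Hspa8 and Hspa1a rose by 1.22 ± 0.11 and 2.32 ± 0.22, and Hspa1b by 1.54 ± 0.15. The last 2 are near-identical copies whose shared reads were left out, and part of the exons of Hspa1a overlaps those of another gene. Without GFPneg replicate 8, 14 members rose and 0 fell. For 16 of the 26 members every GFPpos library stood above every GFPneg library (chance gives 0.397% per gene). The camera call (adjusted p = 1.2e-30) held with an estimated correlation (adjusted p = 0.040).

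Of 29 interferon response genes, 9 rose and 1 fell (14 and 2 adjusted over the list alone). Usp18 rose by 1.47 ± 0.23, Stat2 by 1.33 ± 0.22 and Cxcl10 by 1.28 ± 0.23, and the call of the list (adjusted p = 1.6e-07) was lost with an estimated correlation (adjusted p = 0.138). Leaving out 1 library gave 6 to 11 rises, with 6 without GFPneg replicate 3, 4 or 8 or GFPpos replicate 3. Falls numbered 3 without GFPpos replicate 4 and 0 without GFPneg replicate 3, 8 or 9 or GFPpos replicate 8. YAP and TEAD targets moved both ways, with 6 rises and 4 falls among 20 (6 and 6 adjusted over the list alone): Ccn1 rose by 1.08 ± 0.19 and Tgfb2 by 0.96 ± 0.16, while Csrp1 changed by -0.90 ± 0.13 and F3 (tissue factor) by -0.68 ± 0.12. Rises among them numbered 3 without GFPneg replicate 3, 8 or 9 or GFPpos replicate 2, as without both libraries numbered 2, where 2 fell. The YAP list's median was 0.22 and its mean -0.12, with no camera call (direction up, adjusted p = 0.47).

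Several markers of connective tissue cells were lower in GFPpos. Of 16 stellate cell, fibroblast and smooth muscle markers, 6 fell and 1 rose, with the same counts adjusted over the list alone. Dcn, which encodes decorin, fell from 61.3 ± 22.4 to 11.4 ± 5.04 CPM, Col1a2 from 98.6 ± 43.9 to 14.1 ± 7.46 CPM and Ecm1 from 67.6 ± 10.9 to 11.6 ± 4.00 CPM, whereas the pericyte gene Rgs5 rose by 1.89 ± 0.36. Falls numbered 3 without GFPneg replicate 4 or GFPneg replicate 8. Of 11 mesothelial markers, 3 fell and 1 rose (3 and 1 adjusted over the list alone). Msln (mesothelin) fell from 205 ± 57.6 to 19.1 ± 10.4 CPM and Igfbp5 changed by -3.22 ± 0.36. The rise was that of Cav1 (0.68 on the log2 scale), lost without GFPneg replicate 4 or 8 or GFPpos replicate 2, 8 or 9 (adjusted p up to 0.094, without GFPneg replicate 8) and with the replicate block (0.073). Camera calls of both lists (adjusted p = 3.4e-05 and 0.0065) were lost with an estimated correlation (adjusted p = 0.138). Endothelial markers had 1 rise (Egfl7, 1.79 ± 0.42) and 0 falls among 20; the rise was lost with each GFPneg library left out in turn (adjusted p up to 0.086, without GFPneg replicate 8) and with the replicate block (0.055). Without GFPpos replicate 2, 1 endothelial marker fell, and the list's share of counts was higher in GFPpos in 1 of 5 pairs, that of the libraries numbered 2. Macrophage markers had 0 rises and 1 fall among 6 (Cd68, -1.41 ± 0.27), with the same counts adjusted over each list alone.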

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

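The tests of hepatocyte RNA in single libraries, of handling, of immune cells, of low-level drop-out and of the share of biliary cells, and the fits with the stress covariate, were chosen only after the results were seen. Of 270 groups of 5 libraries examined for a library far from the rest, 32 held one. For independent, normally distributed values chance would give about 13.5 (1 in 20). CPM values need not be normal and some list shares contain the named genes, so an excess over chance was not tested. GFPpos replicate 2 accounted for 10 of the 32. It was highest in its group for the share of counts on the endothelial list (0.0308%, next 0.00726%), Pecam1 (9.26 CPM, next 2.28), Laptm5 (14.4, next 1.31), Egfl7 (32.3, next 13.7), Sds (5.70, next 2.54), Proc (388, next 263), Arl13b (169, next 88.3), Cep290 (59.4, next 23.3) and Notum (4.04, next 1.16), and lowest for Col1a2 (1.22 CPM, next 14.4). Both libraries numbered 4 stood apart for the plasma protein genes Trf (410 CPM in GFPneg, 1737 in GFPpos) and Ahsg (29.8 and 127).

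In GFPneg, replicate 4 was also highest for Dcn (101 CPM), for the share of counts on the stellate list (0.0735%) and for that on the p53 list (0.273%), and lowest for Muc20 (18.6 CPM). GFPneg replicate 2 was highest for Atoh8 (13.7 CPM), replicate 8 for Flt4 (13.5 CPM) and replicate 9 for Aqp1 (499.5 CPM), Ncam1 (15.4 CPM), Plac8 (243 CPM) and Mmp9 (4.70 CPM), and replicate 9 was lowest for Proc (63.1 CPM). In GFPpos, replicate 3 was highest for Gcnt3 (16.8 CPM), Muc20 (3.52 CPM) and Ltf (3.16 CPM), replicate 8 for Galnt6 (3.20 CPM) and Perp (286 CPM), and replicate 4 for Npc1l1 (1.66 CPM) and Mrc1 (2.20 CPM).

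Among 100 of the 126 splits of the 10 libraries into 5 and 5, only the real one (1 split) called 907 genes. The highest other called 0, also among the 13 drawn that part all 5 pairs. If libraries could be swapped freely, this argues against chance for the count of changed genes. With the libraries taken as pairs the splits cannot decide it, since swaps within 5 pairs allow no p below 0.0625. Every other split also mixes the 2 groups, so a group difference adds to its spread and can lower its count. Chance cannot be excluded for the count of lists, since 10 of 100 splits, the real one included, called at least its 13 lists. The highest other called 17, a split that parts all 5 pairs. Library size did not account for the calls, as 97.8% of them stayed called after all libraries were thinned to the smallest total.

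Of 28 hepatocyte genes 7 were called higher in GFPpos, and of the 10 most abundant hepatocyte transcripts 3, while the camera calls of both lists ended with an estimated correlation (adjusted p = 0.138). The lists overlap, as all of the 10 but Apoc1 are in both. All 10 of these transcripts had positive fold changes and 0 of 10 were lower by more than 2 SE, with a scatter (SD 0.946) within their median SE of 1.23. This is the pattern set beforehand for hepatocytes or their free RNA in the sort, but it covers all libraries together. The share stayed higher in 10 of 10 leave-one-out settings, so no single library decided it. In GFPpos replicates 3, 4, 8 and 9, Apoa1, Apoa2, Apoc3, Fabp1 and Serpina3k were low beside the 7 called hepatocyte genes. Their levels would allow a median of only 3.88% of the measured levels of these genes, even if all of their level in GFPpos replicate 2 came from hepatocytes. This argues against hepatocyte RNA with the ratios of GFPpos replicate 2 as the source there. The 5 transcripts were chosen after their values were seen, so a low percentage was in part set by that choice. Ahsg, also among the 10, was highest in GFPpos replicate 4 (127 CPM), so hepatocyte RNA with other ratios stays open. In GFPpos replicate 2, hepatocyte RNA beside that of Kupffer and endothelial cells stays open, despite the EpCAM sort. With the level of the stress list as a covariate 43.7% of the called genes' median log2 fold remained (2.12 with a median SE of 0.29 before, 0.93 with 0.70 after), the calls ended as the fold fell and the SE rose, and as that level correlated with the group at 0.95, stress and group cannot be told apart here. The difference that the design names, between cells with and without the vector's marker, was not tested apart from these and stays open.

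Most immediate early and heat shock genes were higher in GFPpos (17 of 26 called higher, 1 lower). Leukocytes as the whole source are argued against by Ptprc, whose level was at most 0.0155% of that of Fos in a GFPpos library. The share of counts on the stress list was highest in GFPpos replicate 2 (4.83%) and lowest in replicate 8 (2.62%), as was that on the macrophage list (0.0199% and 0.00402%). Yet in replicate 8 the macrophage share lay below that of each GFPneg library (lowest 0.00551%) and the stress share above (highest 1.83%). Longer handling or sorting of GFPpos cells could give such a rise. That 0 of 26 members had all GFPpos libraries inside the GFPneg range restates the rise and does not bear on its source. As the labels give no handling time, handling and the cells' own state cannot be told apart. The biological difference between the groups was not tested apart from it.

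Mucin and peribiliary gland genes were lower in GFPpos. Drop-out of low transcripts as the whole source is argued against by the 9 of 17 members with at least 50 CPM in GFPneg, whose median log2 fold change was -2.09. These were picked by their GFPneg level, which can favour falls, and drop-out of the lower members was not tested. A lower share of biliary cells, which would lower biliary genes alike, is argued against as the whole source of this fall by the 34 biliary markers. Their median was -0.042 (SD 1.10), above the -2.19 of the mucin list by 2.15. A smaller fall in that share was not tested, since scaling holds the median of all tested genes near 0 (0.029). Stellate and mesothelial markers, which a lower share of biliary cells would raise, had medians about as low as the mucin list (-1.99 and -2.11). Their shares of counts were lower in GFPpos in 5 of 5 pairs. Only 6 of 16 and 3 of 11 members were called lower, and 1 in each list was called higher. The camera calls of both lists ended with an estimated correlation (adjusted p = 0.138). As Krt7 (-1.52) and Aqp1 (-2.85) fell as well, a difference in the kinds of cells sorted, biliary or other, stays open. With the stress list as a covariate 90.3% of the median log2 fold of the 7 called members remained (-3.37 with a median SE of 0.745 before, -3.05 with 2.13 after), so the calls ended as the SE rose and a part of stress in the fall cannot be told apart from the group. The difference that the design names, between cells with and without the vector's marker, was not tested apart from these and stays open.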

How the results depend on the processing

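The fits without both libraries numbered 2 and with the stress covariate, and the biliary share without Clu and Spp1, were added after seeing the data. Under the replicate block 781 genes were called, 331 higher and 450 lower in GFPpos, of which 666 were among the main 907, and 15 of the 83 named genes that passed the main test lost their call. Scaling by DESeq2's size factors, library size only or upper quartile gave 915, 906 and 939 genes, the share of higher calls moving from 45.1% to between 36.0% and 52.1%. No filter gave 725 and a stricter filter 1068. DESeq2 called 1852 genes (861 higher, 991 lower) and with the block 2788 (985 and 1803), limma voom 1365 (818 lower) and a test against a fold of 1.5 called 238 (75 and 163). In simulated counts DESeq2 without the block made 39 false calls among 111, which may bear on its count of 1852. Those counts were drawn a single time with dispersions estimated by edgeR, and DESeq2 with the block was not simulated. Without both libraries numbered 2, 553 genes were called (202 higher). Leaving out 1 library gave 433 to 966 genes, 165 to 431 higher and 268 to 535 lower, 12 to 17 lists, differences in share of 0.334 to 0.423 (hepatocyte) and 2.12 to 2.47 percentage points (biliary), and adjusted p values of 1.8e-16 to 5.0e-10 for the hepatocyte and 0.36 to 0.99 for the biliary list. Without Alb the hepatocyte difference fell from 0.382 to 0.185 percentage points, and without its list's most abundant member it was 0.333, while the biliary one fell from 2.32 to 1.45, each with an exact p of 0.00794. Without Clu and Spp1 the biliary difference was 0.147 (exact p = 0.651). In the alternatives set beforehand 0 of the 83 changed direction, and 47 kept their call in all of them.

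An estimated correlation left 3 called lists and ended the call of the hepatocyte list (adjusted p = 0.138). The sign-flip test of the same-numbered differences (replicate block) gave an exact p of 0.0625, the smallest that 5 pairs allow, for the differences in share of 0.382 (hepatocyte) and 2.32 percentage points (biliary), so it could not pass. Fry, which does not compare a list with other genes, called 13 lists (5 up, 8 down), of which 10 were among the main 13. Not called were lipoprotein (adjusted p = 0.061), complement (0.10) and urea cycle (0.072), and added, all down, were progenitor (0.0090), tuft cell (0.0082) and p53 (0.023). The block called 14 lists and kept 12 of the main 13. It added the MHC class II (adjusted p = 0.00084) and cholesterol synthesis (0.027) lists, which without the block had 0.47 and 0.57 with an estimated correlation. Among named genes it added Lcn2 (log2 fold change -1.01, adjusted p = 0.024) and Atf4 (0.55, adjusted p = 0.016) and changed no other call than the 15 it ended. Mmp9, not called (0.34, adjusted p = 0.94), turned to -0.90 with the block, -0.91 by DESeq2 with the block, -1.54 by limma voom, -0.49 without GFPpos replicate 2, -0.0799 without GFPpos replicate 9 and -0.66 without both libraries numbered 2, not called in any of these.

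With the stress list's level as a covariate, which nearly equals the group, edgeR called 0 genes (0 higher, 0 lower), 822 had an unadjusted p under 0.05, and 21 named genes had the opposite sign, all with adjusted p of at least 0.915: Serpind1 -1.68, Kcne3 -1.06, Klf2 -0.0552, Fos -0.25, Nrep -0.24, Ret 1.45, Slc9a4 2.08, Galnt6 1.66, Npc1l1 1.05, Hnf4a 0.76, Nr0b2 -2.20, C1ra -0.12, Itga6 0.17, Laptm5 -4.68, Lyz2 -3.97, Aldh1a2 0.10, Srxn1 0.30, Arl13b -0.34, Cep290 -0.89, Ift57 -0.0857 and Mmp9 -6.16. Fos and Klf2 are members of the stress list, so the covariate takes up much of their difference by construction. The cause of other changes was not tested. At this depth and spread, and with 200 genes changed, the simulation recovered 16.4% of genes changed by a fold of 2. Genes that missed the threshold are therefore not shown to be unchanged.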

Other observations

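Among 20 glutathione and NRF2 targets 3 fell and 0 rose (4 and 1 adjusted over the list alone), with Me1 (malic enzyme) at -1.02 ± 0.15 and Gsta4 at -1.91 ± 0.29 on the log2 scale, and the camera call (adjusted p = 0.0043) was lost with an estimated correlation (adjusted p = 0.138). Falls numbered 2 without GFPneg replicate 3, and 1 rose without GFPpos replicate 4. Of 19 p53 and DNA damage genes 3 rose and 3 fell (3 and 4 adjusted over the list alone), among them Pmaip1, a pro-apoptotic gene, from 189 ± 30.5 to 25.7 ± 10.5 CPM. These counts depended on single libraries, with 0 rises without GFPneg replicate 2 or 8 or GFPpos replicate 3 or 9, 1 rise without GFPneg replicate 3, 4 or 9 or GFPpos replicate 2 or 8, 1 fall without GFPneg replicate 2 or 8, and 1 of each with the replicate block. Of 17 NF-kB and acute inflammation genes 2 rose and 1 fell (4 and 3 adjusted over the list alone). Socs3 rose by 1.01 ± 0.16 and the chemokine gene Cxcl5 changed by -1.97 ± 0.33; without each library but GFPneg replicate 4 and GFPpos replicate 3, 1 rose, and 2 fell without GFPpos replicate 2, 4, 8 or 9 and with the block.

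Myc and Tnfrsf19 were the 2 of 12 Wnt targets that rose (2 adjusted over the list alone), Myc by 0.81 ± 0.13. The call of Tnfrsf19 was lost without each library but GFPneg replicate 4 and GFPpos replicate 3 (adjusted p up to 0.120, without GFPneg replicate 8). In the cilia list 1 of 31 genes rose (Arl13b, 1.80 ± 0.29; 1 adjusted over the list alone), and 2 without GFPpos replicate 4 or 8. Of 20 unfolded protein response genes 2 rose (3 rose and 2 fell adjusted over the list alone), including the chaperone gene Hspa5 by 0.78 ± 0.15, but 1 rose without each library except GFPpos replicates 3 and 4, and 1 fell without GFPpos replicate 2. Plac8 was the 1 of 3 neutrophil and monocyte markers that fell (2 adjusted over the list alone); 0 fell without GFPneg replicate 8 or 9 or GFPpos replicate 8 or 9, and 2 without GFPpos replicate 3.

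Epithelial-mesenchymal and matrix genes had 1 rise and 4 falls among 19 (1 and 5 adjusted over the list alone), with 1 fall without GFPneg replicate 4 or 8, 2 without GFPpos replicate 8, and the rise kept in number only without GFPneg replicate 4 or GFPpos replicate 8 or 9. Pericentral genes had 1 rise among 11 (1 rise and 2 falls adjusted over the list alone), with 0 rises without GFPneg replicate 2, 8 or 9 or GFPpos replicate 4, 8 or 9, and 1 fall without GFPpos replicate 4 or 9. Bile acid genes had 2 rises among 19 (3 adjusted over the list alone), 1 without GFPneg replicate 9 or GFPpos replicate 2, 3 or 8, 0 without GFPneg replicate 2, 3, 4 or 8 or GFPpos replicate 9, and 0 with the replicate block.

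In 12 further lists edgeR called 0 genes: proliferation (30), Notch (18), cholesterol synthesis (20), MHC class II (8), urea cycle and amino acid catabolism (19), tuft cell (9), lymphocyte (6), erythroid (5), platelet (2), sex-linked (5), mitochondrially encoded (7) and ribosomal protein genes (40). Adjusted over the list alone, 3 urea cycle genes rose and 1 fell, and 1 tuft cell gene fell. Leaving out 1 library gave 1 Notch rise (GFPpos replicate 9), 1 urea cycle fall (GFPpos replicate 3 or 9) and tuft cell falls (1 without GFPneg replicate 8 or GFPpos replicate 2, 3, 4 or 9, 2 without GFPpos replicate 8). These 12 lists hold 169 measured members, of which 27 had an unadjusted p under 0.05, 18 were called by DESeq2 and 10 by limma voom. The urea cycle list was called by camera (direction up, adjusted p = 0.018), a call lost with an estimated correlation (adjusted p = 0.33), and the replicate block called 2 of its genes higher and 1 lower. The block also called 2 of the 8 MHC class II genes higher, all 8 had positive fold changes without it, and the list's share of counts was higher in 5 of 5 pairs. Median, mean and test differed in sign for the Wnt (median and mean -0.16 and -0.38, test up), NF-kB (0.01 and -0.27, test up), Notch (0.03 and -0.03, test up) and sex-linked lists (-0.14 and -0.24, test up), none of them called.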
